A study of Homo sapiens with 2 samples.

How the data were processed

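Expression was measured with an Affymetrix array on tumour RNA from LNCaP xenografts in NOD/SCID mice. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made from 6 ug of it. Per the series' design text, 24 mice were injected and divided into arms of 12 when tumours had reached 5 mm, 3 days after injection, although the same text opens by naming 12 mice. Treatment lasted 30 days. Each arm has 1 array. Whether an array holds 1 tumour or a pool is not given in the sources used here.

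The deposited value table holds 1 intensity per probe set and array. Per the submitters' processing notes the values come from RMA, which corrects background, normalizes quantiles and summarises probes; its version and software are not given in the sources used here. The intensities are on a linear scale, which was read from the values (17.4 to 6088), since log2 RMA values do not reach such numbers. Whether the authors added an offset is unknown. The lowest readings sit on a floor near 17, and the SD of the difference between arrays was 0.03 on the log2 scale in the dimmest eighth of probe sets against 0.29 in the brightest. Log2 differences of dim genes are therefore compressed. Depth has no meaning for arrays; the number of arrays limits the precision.

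Probe sets were named from a platform annotation table that lists 15835 of the 44629 probe sets, or 35.5%, each with 1 gene symbol and none with several. The other 28794 probe sets are unnamed here, which does not mean that they have no gene. All 15835 Entrez identifiers were found in the RefSeq gene table of GRCh38.p14, and 0 symbols needed updating. The genome build behind the array's annotation is not named in the sources used here, so no coordinates are given. No control probe sets were identified in the table, so the planned 3'/5' and spike-in checks were not made.

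From the deposited values, log2 was taken first, as the preset design asked for linear data. A probe set was kept where the higher of its 2 values was at or above the 40th percentile of all values, an intensity of 20.9. Of several probe sets of a gene, the one with the highest mean stood for the gene; 503 measured genes had 2 or more. The difference is cisplatin minus PBS. The size mark was 2-fold. With 1 array per arm no test was run. Each gene list's median was placed among 10000 random lists of equal size drawn from measured genes in 20 bins of mean expression, and lists under 5 measured members were reported as values only. A list was called outside its random range under percentile 2.5 or over 97.5. Of the 49 lists, 3 had no measured member: histones, proteasome subunits and red cell markers.

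The lists, the filter, the size mark, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 largest rises and falls among genes whose probe sets all passed 2-fold, which gave 0 genes, and left genes with 1 probe set as a count; up to 4 genes per list with the largest differences; and 30 preset genes, of which 12 were measured, 2 fell below the filter and 16 had no probe set named here, some of which are not reported here. The genes past 2-fold with 1 probe set, and further list members given as examples, are named after their values were seen. The alternatives were no filter, a filter at the 60th percentile, a filter on the mean, median centring, a loess of difference on mean intensity (span 0.3), a further quantile normalization, the mean over a gene's probe sets, an offset of 32 on the linear scale and unmatched random lists. Subtracting 16 from every value, for genes reaching 32, was added after seeing the data. Leaving out probe sets by an _x_at or _s_at ending could not be done, because the identifiers carry no such endings. Leaving out replicates and splitting the samples another way were not possible with 1 array per arm.

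The procedure was tested on simulated data with the real genes' means and local spreads. Of 114 unchanged lists, 7 fell outside the percentile marks, and of 38 lists lowered by 0.3 on the log2 scale, 37 were found. Simulated genes varied independently, unlike co-regulated genes. A shift of 0.3 is larger than most list medians called outside their range below, so smaller shifts were not tested. Among 200 genes given a true 2-fold rise above a floor of 16, drawn from the 11895 measured genes, the median apparent fold of those 200 was 1.53. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.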

Results

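The data came from tumours grown in NOD/SCID mice, an immunodeficient strain, from LNCaP cells. LNCaP is an established human prostate cancer cell line that depends on androgen and makes prostate-specific antigen. The mice were not castrated. One arm received cisplatin, a platinum drug that crosslinks DNA, at 5 mg/kg every 3 days for 30 days, and the other received the PBS vehicle. RNA of tumour tissue was profiled on an Affymetrix expression array. There was 1 array per arm, so no difference below has a replicate check, a p-value or a standard error, and each describes these 2 arrays. The value table held 44629 probe sets per array, with a median intensity of 22.3 in the PBS array and 22.4 in the cisplatin array. The lowest intensities were 17.5 and 17.4, and 71.1% of probe sets read under 32 on both arrays. Of 14812 genes named in the annotation used here, 11895 had a probe set above the filter and are called measured. The number of arrays limits the precision of every value.

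The comparison asks what a 30-day course of cisplatin changed in the transcriptome of the tumours. The prostate kallikreins KLK2 and KLK3 were among the genes with the largest deficit in the cisplatin array. KLK2 (transcript cluster 16864628), a prostate serine protease, read 364.0 in the PBS array and 92.0 in the cisplatin array, 3.96-fold lower. KLK3 (transcript cluster 16864616), which encodes prostate-specific antigen, read 1466 and 478, 3.07-fold lower. These genes are close paralogs, so part of their signal may be shared between probes. Of the measured genes, 9 were at least 2-fold higher and 9 at least 2-fold lower in the cisplatin array. At a mark of 1.5-fold, added after the data were seen, 53 were higher and 82 lower. These counts depend on the floor of the values. With an offset of 32 the 2-fold counts were 1 and 4 and the 1.5-fold counts 24 and 24, and with 16 subtracted, chosen after seeing the data, they were 32 and 41, and 249 and 290. Differences over all measured genes had a median of 0.02 and an SD of 0.19 on the log2 scale, and the arrays correlated across probe sets with a Pearson r of 0.986. Genes are not independent replicates.

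The preset rule for the largest differences required at least 2 probe sets that all passed 2-fold, which 0 genes met, and left genes with 1 probe set as a count. The genes past the 2-fold mark are named here all the same, chosen after their values were seen. Besides KLK2 and KLK3, TARP, a prostate transcript of the T-cell receptor gamma locus, was 3.20-fold lower, from 103.9 to 32.4. The probe set of the microRNA gene MIR21 was 2.48-fold lower. ABHD2, a lipid hydrolase gene, was 2.24-fold lower. HERC3, which encodes a ubiquitin ligase, was 2.18-fold lower. The remaining genes on this side were MIR3916, STK39 and ENDOD1, at 2.09, 2.08 and 2.06-fold lower. On the other side, the probe set of MIR2909 was 2.35-fold higher and the pseudogene OCLNP1 2.31-fold higher. OCLN, whose sequence the pseudogene may share, read 101.6 and 132.6. CCL2, a chemokine that attracts monocytes, was 2.24-fold higher, from 43.0 to 96.4. MIR891A was 2.15-fold higher, NIPSNAP3A 2.06-fold and NBEAP1 2.04-fold. TP53INP1, a stress protein gene induced by p53, was 2.03-fold higher, from 275.6 to 560.5. WEE2-AS1 was also 2.03-fold higher, from 31.3 to 63.6, and SESN1, a p53-induced inhibitor of growth signalling, was 2.01-fold higher, from 119.7 to 241.1. The lower readings of WEE2-AS1, TARP and MIR21, at 31.3, 32.4 and 35.8, lie near the floor, where folds are compressed. Microarray probe sets named for microRNA genes do not separate the mature microRNA from its precursor.

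**Figure D1:**
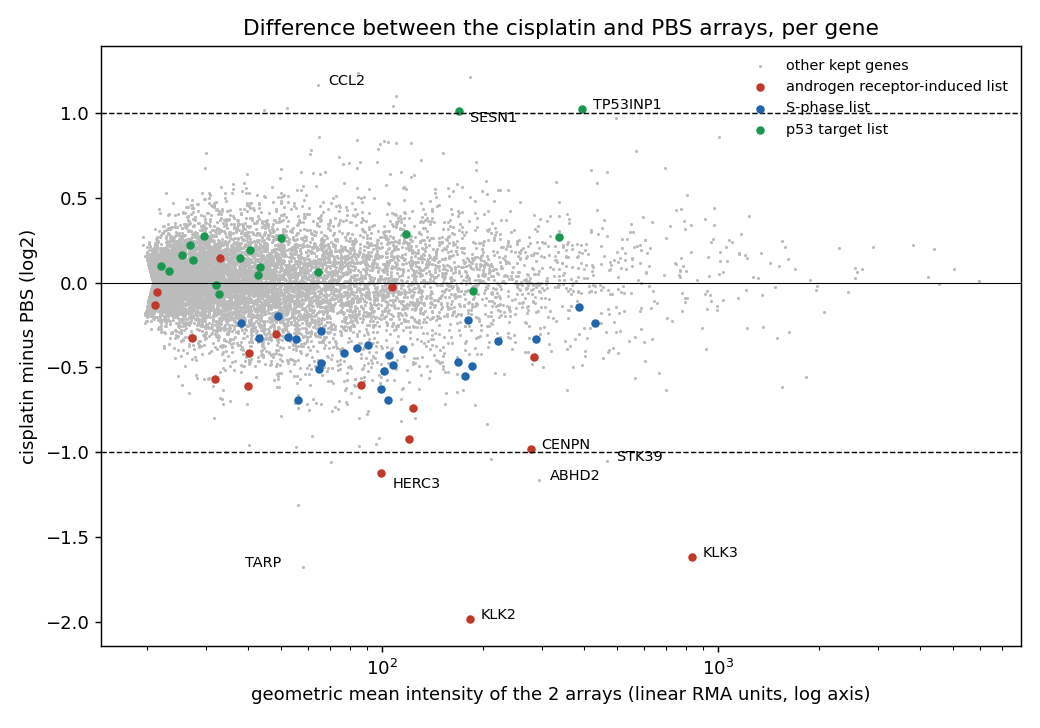
Each point is 1 measured gene, with the geometric mean intensity of the 2 arrays on a log axis (linear RMA units) and the cisplatin minus PBS difference (log2) on the vertical axis. Dashed lines mark 2-fold, colours mark the androgen receptor-induced, S-phase and p53 target lists, and KLK2 and KLK3 lie lowest of the list genes, at -1.98 and -1.62.

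Gene lists fixed before the data were examined were compared with 10000 random lists of the same size, matched on mean expression. Of 49 lists, 38 had at least 5 measured members. The median of 12 of these lay outside the central 95% of their random lists, 10 below and 2 above, where chance alone would give about 1.9. A percentile states where the list's median fell among its random lists, and random lists lack the co-regulation of real ones. An interval given with a median is a 95% bootstrap interval over the list's members, which leaves out the spread between tumours.

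Genes that the androgen receptor induces were lower as a group in the cisplatin array. Of 30 listed genes, 17 were measured. Of these, 16 were lower, 8 of them by at least 1.5-fold, and 1 was higher. The list's median was -0.57 on the log2 scale (interval -0.92 to -0.30), below all 10000 random lists (percentile 0). The size depended on the treatment of low values, with a median of -0.34 with an offset of 32 and -0.94 with 16 subtracted. The subtraction also leaves out members that do not reach 32, such as STEAP4 and MAF. After KLK2, KLK3 and HERC3, the largest differences were in CENPN, a kinetochore gene, which read 389.2 and 197.5, and in ZBTB10, which read 166.1 and 87.6. C1orf116 read 159.5 and 95.5. KLK4, another prostate kallikrein, read 330.7 and 243.7. FKBP5, a co-chaperone of steroid receptors, read 38.9 and 26.2. The exception was GNMT, a glycine methyltransferase, at 31.3 and 34.7. Among genes that androgen represses, only 3 were measured. FOLH1, which encodes prostate-specific membrane antigen, read 1082 and 1421, and DDC, a decarboxylase of amine synthesis, read 33.5 and 45.2. BCL2 read 30.1 and 29.6. TMPRSS2 had no probe set named here.

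Genes of the S-phase list were lower in the cisplatin array. All 26 measured S-phase genes read lower, and the list's median was -0.39 (interval -0.48 to -0.33), below all 10000 random lists (percentile 0). MCM5 and MCM10, parts of the replication helicase machinery, were each 1.61-fold lower. CDC45, another helicase component, was 1.54-fold lower, and MCM4 was 1.46-fold lower. PCNA, the sliding clamp of DNA polymerase, read 322.7 and 256.2. Genes of mitosis differed less. Of 29 measured, 24 were lower and 5 higher, with a median of -0.09 (interval -0.18 to -0.07) at percentile 1.41. Within that list AURKB, a mitotic kinase, was 1.51-fold lower and MKI67, the Ki-67 proliferation antigen, 1.44-fold lower. TOP2A, a DNA topoisomerase, was 1.27-fold lower and CDK1 1.28-fold lower. CCNB1, which encodes cyclin B1, was higher, at 375.1 and 465.3.

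Genes of damage signalling, crosslink and recombination repair and mismatch repair had medians below their random ranges, and translesion synthesis genes, at percentile 25.1 with a median of -0.05 over 6 measured, did not. In the damage signalling list, 14 of 17 measured genes were lower, with a median of -0.18 (interval -0.38 to -0.04) at percentile 0.31. CLSPN, the checkpoint adaptor claspin, was 1.42-fold lower. MRE11, a nuclease that senses broken ends, was 1.37-fold lower, and TOPBP1 and MDC1 were each 1.36-fold lower. In the crosslink and recombination repair list, 10 of 13 were lower, with a median of -0.18 (interval -0.33 to -0.05) at percentile 0.41. The median was -0.11 with an offset of 32. RAD54L, a recombination motor protein, was 1.53-fold lower and EME1 1.42-fold lower. BARD1, the partner of BRCA1, was 1.39-fold higher. The mismatch repair list had 6 measured genes and a median of -0.21 at percentile 2.06, but its interval, -0.49 to 0.17, spanned 0. EXO1, a repair exonuclease, was 1.51-fold lower in it and PMS2 1.20-fold higher. Whether the lower medians of these signalling and repair lists are separate from that of the S-phase list was not tested. Nucleotide excision repair, which removes platinum adducts, had only 3 measured members. RAD23B read 492.5 and 605.6, XAB2 read 51.0 and 45.2, and UVSSA read 25.9 and 25.1. No probe set named here represented ERCC1, XPA, BRCA1 or BRCA2.

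Targets of p53 were higher as a group. Of 19 measured targets, 16 were higher and 3 lower, with a median of 0.15 (interval 0.07 to 0.26) at percentile 99.9. The size depended on the treatment of low values, with a median of 0.073 with an offset of 32 and 0.27 with 16 subtracted. The subtraction also leaves out members that do not reach 32, such as BBC3 and SESN2. TP53INP1 and SESN1 were the only members past 1.5-fold. CCNG1, a p53-induced cyclin, read 106.2 and 129.9, and TP53I3 read 26.8 and 32.4. GDF15, a stress cytokine gene, read 190.1 and 183.7. Without TP53INP1 and SESN1 the list lay at percentile 99.4. CDKN1A and MDM2 had no probe set named here. Genes promoting apoptosis had a median of 0.11 at percentile 95.9, inside the random range, and genes inhibiting it a median of 0.08 at percentile 85.0. The promoting list passed the upper mark after quantile normalization and with an offset of 32, at percentiles 97.9 and 97.8. MCL1, a survival protein gene, read 45.9 and 49.3.

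The NF-kB and cytokine list was the second list above its random range, with 10 of 13 measured genes higher and a median of 0.12 (interval 0.06 to 0.23) at percentile 98.4. CCL2 and NFKB1, the gene of a subunit of NF-kB, were past 1.5-fold, at 2.24 and 1.64-fold higher. CCL20 was 1.27-fold higher. CXCL8 read 18.9 and 19.5, below the filter, and IL6 had no probe set named here. This list returned to its random range, at percentile 96.5 with a median of 0.046, when an offset of 32 was added to every value. The list's median was 0.59 with 16 subtracted, but that leaves out most of the 13 members, such as RELB and IL32, which do not reach 32. Only CCL2, CCL20, NFKB1, NFKB2 and IER3 remained, so this value does not describe the whole list. Markers of other cell types were set beside this list. The macrophage list had a median of 0.02 at percentile 45.7, the endothelial list 0.12 at percentile 97.3 and the keratinocyte list 0.12 at percentile 96.8. The endothelial list passed the upper mark in 3 alternatives, up to percentile 98.2 without the filter, and the keratinocyte list passed it with the offset, at 98.0. Most of these marker probe sets read under 32 on both arrays, as with CD14 at 21.3 and 20.6, while CD68 read 40.4 and 36.2.

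Fatty acid synthesis genes were lower in the cisplatin array. Of 15 measured, 13 were lower, with a median of -0.23 (interval -0.29 to -0.03) at percentile 0.02. The median was -0.38 with 16 subtracted, which also leaves out members that do not reach 32, such as ACACB and MLXIPL. The fatty acid elongases ELOVL5 and ELOVL7 were 1.76 and 1.74-fold lower, the second with a cisplatin reading of 23.9, near the floor, where folds are compressed. ACACA, the carboxylase of the first committed step, read 312.5 and 235.8, and FADS2, a desaturase, was 1.32-fold lower. Cholesterol synthesis genes had a median of -0.08 at percentile 8.73, inside the matched random range, and lay at percentile 2.13 of unmatched random lists. Luminal epithelial genes had a median of -0.13 at percentile 1.76, with 10 of 15 lower and an interval of -0.39 to 0.08. SPDEF, a prostate epithelial transcription factor, was 1.45-fold lower, and the claudins CLDN3 and CLDN7 were 1.38 and 1.31-fold lower. EPCAM read 258.1 and 246.6, KRT18 read 224.4 and 243.6, and FOXA1 read 90.2 and 92.9. The luminal list returned to its random range with an offset of 32 (median -0.06, percentile 5.66) and with 16 subtracted (median -0.07, percentile 17.3). The subtraction leaves out the list members KRT19 and CLDN4, which do not reach 32.

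**Figure D2:**
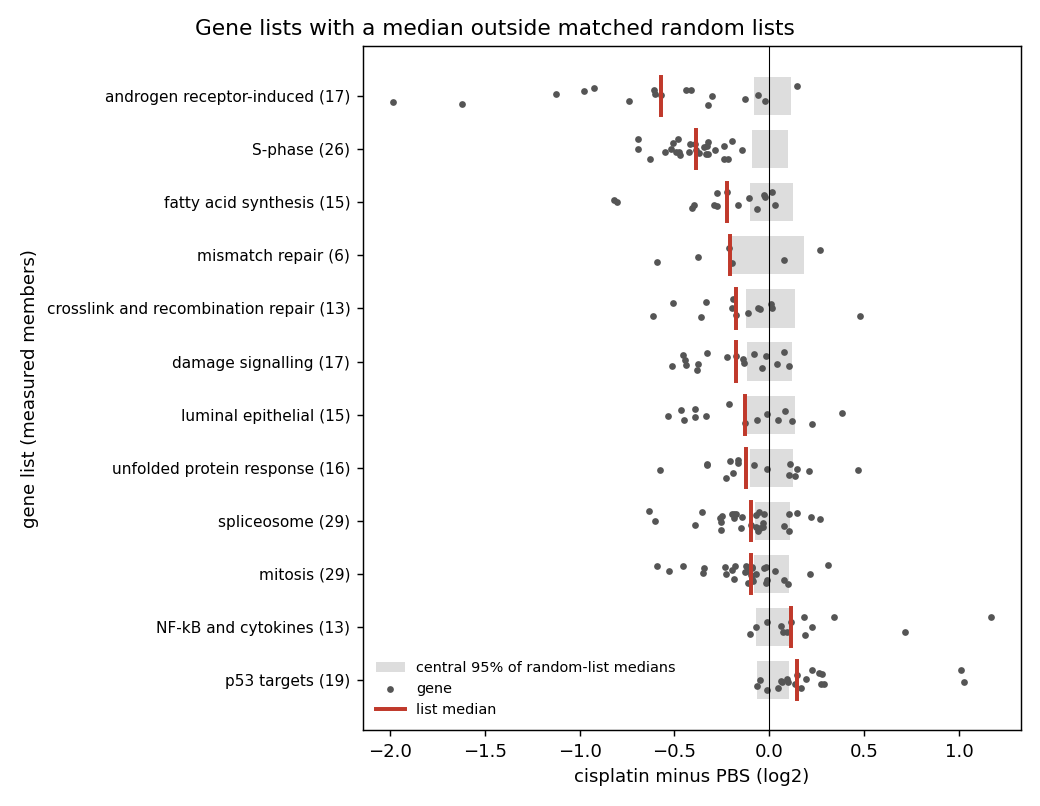
Each grey point is 1 measured gene of a list, placed by its cisplatin minus PBS difference (log2), the red bar is the list's median, and the grey band holds the central 95% of medians of 10000 random lists matched on expression. The androgen receptor-induced and S-phase lists lie farthest below their bands, with medians of -0.57 and -0.39, and the p53 and NF-kB lists lie above theirs.

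The unfolded protein response and splicing lists made up the rest of those below their random ranges. The former had a median of -0.12 at percentile 1.06, with 10 of 16 genes lower, but its interval, -0.21 to 0.11, spanned 0. HYOU1, a chaperone of the endoplasmic reticulum, was 1.49-fold lower, while ATF3, a stress-induced transcription factor, was 1.38-fold higher. This list returned to its random range after a further quantile normalization, at percentile 3.34, and with 16 subtracted, at percentile 2.78. Its median was -0.07 with an offset of 32. In the splicing list 23 of 29 genes were lower, with a median of -0.09 at percentile 1.19. HNRNPA1 and HNRNPC, which bind pre-mRNA, were 1.55 and 1.52-fold lower, and both have pseudogenes that probes may read.

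The other 26 lists had medians from -0.08 to 0.14 and percentiles from 3.67 to 97.3. The neuroendocrine list, which bears on a lineage that prostate tumours can adopt, had a median of 0.03 at percentile 49.4. CHGA, the gene of chromogranin A, read 25.2 and 23.1, and SYP, the gene of synaptophysin, read 23.1 and 23.9, both near the floor. GRP read 29.0 and 37.8, and VGF read 35.5 and 26.9. The mesenchymal list had a median of -0.06 at percentile 3.67. In it SNAI2, a transcription factor of the epithelial to mesenchymal transition, read 56.0 and 28.9, the latter near the floor, and VIM read 28.9 and 33.5. Glutathione and NRF2 genes had a median of 0.07 at percentile 93.3, and passed the upper mark after quantile normalization and with an offset of 32, at percentiles 98.1 and 98.2. TXN, the gene of thioredoxin, read 987 and 1173, and GSTA1 read 163.3 and 217.4. Metallothioneins, which bind platinum as well as other metals, had a median of 0.14 at percentile 93.0, led by MT1G at 136.7 and 205.0, and their near-identical copies can share signal. Hypoxia genes lay at percentile 24.3, with VEGFA at 38.5 and 33.8. The interferon list lay at percentile 64.8 and ribosomal proteins at percentile 33.2. Platinum transport had 2 measured members, ATOX1 at 34.2 and 34.6 and TMEM205 at 259.5 and 220.8. SLC31A1, ABCC2 and ATP7B had no probe set named here.

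The remaining cell type lists with at least 5 measured members lay near the middle of their random ranges. The smooth muscle and pericyte list lay at percentile 54.6 and the adipocyte list at percentile 48.1. The fibroblast, lymphocyte and skeletal muscle lists had 4, 3 and 3 measured members, and no red cell marker was measured. In a xenograft the cells of these lists belong to the mouse, and a human array sees them only where its probes match mouse transcripts. The brightest marker was FN1, the gene of fibronectin, which read 688.7 and 467.3, 1.47-fold lower. The other measured fibroblast markers, THY1, FBLN1 and BGN, read under 32 on both arrays. Whether the FN1 signal came from mouse or LNCaP cells was not tested. Reference genes had a median of 0.06 at percentile 76.4, and went both ways. IPO8 was 1.33-fold higher, at 92.7 and 123.4, PPIA was 1.15-fold lower, and HPRT1 read 129.4 and 117.9. GAPDH read 31.7 and 33.1, close to the floor.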

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

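Probe sets without a gene name in the annotation used here entered none of the gene counts or gene lists above. Of these 28794 probe sets, taken without a filter, 42 were at least 2-fold lower and 6 at least 2-fold higher in the cisplatin array. Among the 11895 measured genes, the numbers were 9 and 9. The probe sets given by identifier were chosen after their values were seen. There is no other control array to set these counts against. The lowest were 17056823 and 17056813, whose readings were nearly equal to each other, from 101.1 to 24.1 in both. Their identifiers stand on either side of that of TARP, 17056817, which fell from 103.9 to 32.4. Whether they read the same locus was not tested. The highest were 16662357, from 83.0 to 197.7, and 16968675, from 109.4 to 258.0.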

How the results depend on the processing

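The subtraction of 16 and the 1.5-fold mark were chosen after seeing the data. With 1 array per arm, no alternative tests replication, and signal near the floor limits what can be said of neuroendocrine and host cell genes. No paired analysis was possible because each arm has 1 array. Leaving out probe sets by an _x_at or _s_at ending was not run, because the identifiers carry none. With an offset of 32 the genes at least 2-fold higher and lower numbered 1 and 4, and those past 1.5-fold 24 and 24. With 16 subtracted they were 32 and 41, and 249 and 290, and 1 gene, MIR103A2, had probe sets that all passed 2-fold. The same 9 higher and 9 lower genes stayed past 2-fold under the 3 other filters, quantile normalization, means over probe sets and 16 subtracted, and 8 and 9 did with median centring, 7 and 9 with loess. The offset gave medians of -0.30 for S-phase and 0.046 for NF-kB. Subtracting 16 gave -0.94 for the androgen receptor-induced list, -0.49 for S-phase, -0.38 for fatty acid synthesis, 0.27 for p53 targets, 0.59 for NF-kB, 0.18 for apoptosis inhibitors and 0.083 for reference genes. The offset compresses all log2 differences. The subtraction widens those of the genes it keeps, but also drops genes that do not reach 32, leaving 6618 of 11895. List medians with 16 subtracted therefore mix both changes, and that of NF-kB rests on a minority of its members. The other 352 list medians stayed inside their bootstrap intervals, which unmatched random lists leave as they were, and none of the 12 lists outside the random range changed sign. The androgen receptor-induced and S-phase lists stayed at percentile 0 under all 10 alternatives. The fatty acid, damage signalling, crosslink repair, mismatch repair, mitosis, splicing and p53 lists also kept their side of the marks in all 10. Median centring shifts a list and its random lists alike, so it could not change a percentile. The loess largely does the same to lists matched on expression. The luminal list returned to its random range with the offset and with 16 subtracted (percentile 17.3), the unfolded protein response list with quantile normalization and with 16 subtracted (percentile 2.78), and the NF-kB list with the offset. Apoptosis promoters and glutathione genes passed the upper mark with quantile normalization (percentiles 97.9 and 98.1) and with the offset (97.8 and 98.2). Endothelial markers passed it in 3 alternatives, up to percentile 98.2, and keratinocyte markers with the offset, at 98.0. Cholesterol synthesis and ribosome biogenesis passed the lower mark against unmatched lists, at 2.13 and 1.62. The cause of these changes of side was not tested. KLK2 ranged from -2.19 with 16 subtracted to -1.67 with the offset, and KLK3 from -1.67 with loess to -1.55 with the offset.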

Other observations

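The tests of the luminal list against the androgen list, of S-phase against mitosis and of the shortened p53 list were chosen after their values had been seen, as were the genes and groups of this paragraph. Small Cajal body RNAs, which guide modification of spliceosomal RNA, were lower in the cisplatin array, a family noticed among 139 groups of genes sharing a symbol stem. Of 20 measured, 15 were lower, with a median of -0.17, below all 10000 random lists (percentile 0). SCARNA22 read 441.4 and 284.4, and SCARNA10 read 82.1 and 57.1, while SCARNA9 read 574.7 and 582.0. Single genes outside this family were RMRP, the RNA of a ribonuclease complex, at 871 and 563, and SNAR-C1 at 1925 and 1254. MicroRNA genes as a class, 427 measured, lay inside their random range at percentile 23.2. Transcribed pseudogenes, 309 measured, lay just above theirs, at percentile 98.25 with a median of 0.038. The group sharing the stem MCM, with 11 of 11 members lower, had the lowest median of these groups, at -0.43. After a further quantile normalization 10 of 11 were lower. MCM2 to MCM7 and MCM10 already stand in the S-phase list, and a shared stem does not make every member a helicase gene. Under the other filters and scalings the small Cajal body RNAs kept a negative median. It ran from -0.62 with 16 subtracted to -0.07 with the offset of 32. The subtraction kept only 11 of these RNAs, 7 of them lower. The MCM median ran from -0.50 to -0.33. Of the 139 groups, 15 lay outside their random ranges, where chance would give about 6.95. Among genes chosen after their values were seen, IGF1R, the receptor of insulin-like growth factor, read 48.6 and 24.3. The replication genes TICRR and E2F8 were 1.93 and 1.87-fold lower.

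The second gene lists were written after the main results but before the values of their members were looked at, except that IDI1, in the androgen list, also stood in the cholesterol list. CCNE2 was taken out of the E2F list after its value was seen, because the S-phase list already held it. The FOXO list leaves out targets whose values had been seen. None of the second lists was rerun under the alternatives. Many members of the FOXO and androgen lists, such as HBP1 and PGC, read under 32 on both arrays.

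The lower androgen receptor-induced genes are the pattern with the largest differences. For an intensity-dependent bias between the arrays, the list was corrected with the loess and stayed at percentile 0. The random lists were already matched on mean expression, so a bias by intensity alone would shift them along with the list. Such a bias would not give the list's place among them, and the loess correction adds little to the main comparison. For a lower share of LNCaP RNA in the cisplatin sample, the luminal list was set against the androgen list. The luminal median lay 0.44 above that of the androgen list, at percentile 99.9 of 10000 shuffles of list labels. Both medians were known beforehand, and quantile normalization can remove a fall shared by most human genes. This comparison therefore cannot decide on a lower LNCaP share. Lower androgen receptor output is consistent with a second list of androgen-induced genes, in which 12 of 15 measured genes were lower (median -0.24, percentile 0), among them GREB1 at 38.9 and 25.5 and UAP1 at 528.9 and 389.1. A difference between the tumour samples or hybridisations unrelated to the drug cannot be told apart from a drug effect with 1 array per arm.

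The lower S-phase genes may reflect lower output of E2F-driven genes as a hypothesis. In a second list of such genes 17 of 18 measured were lower (median -0.32, percentile 0), led by ASF1B at 100.6 and 61.3. Fewer cycling cells with all phases lowered alike would lower the S-phase and mitosis lists by as much. The S-phase median lay 0.29 below the mitosis median (difference -0.29), lower than all 10000 shuffles of list labels. In these arrays the lists were thus not lowered alike. The comparison was chosen after both medians were known, so it is no test of fewer cycling cells. A shift in the share of cells in each phase stays open, as does a chance difference between the tumour samples.

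SESN1 and TP53INP1 stood far above the rest of the p53 list, and both are also known targets of FOXO transcription factors. A second list of FOXO targets had a median of 0.11 at percentile 99.5, with 16 of 19 measured genes higher. TXNIP, its largest rise, read 195.7 and 286.0, while ERBB3, BCL6 and INSR were lower. FOXO activity would give such a position, but this list was not rerun with the offset or the subtraction. The p53 list without SESN1 and TP53INP1 lay at percentile 99.4, which is equally consistent with p53 activity across its targets. SESN3 and ARRDC3, related growth-restraining genes seen before the second list was written, were 1.78 and 1.70-fold higher. Both explanations stay open, and neither was tested against variation between tumours.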
